A study of Mus musculus with 2 samples.

How the data were processed

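H3K27ac ChIP-seq, which recovers DNA bound to histone H3 acetylated at lysine 27, was run on regulatory T cells that had experienced inflammation. Per the labels, the cells were 1 biological sample of adult male mouse origin, aged 6 months, of a strain carrying Foxp3CreERT2 and Rosa26YFP. Both libraries carry biological replicate number 1 and the same biosample, and they are numbered 1 and 2 as technical replicates. They are called library 1 and library 2 here. No input library, untreated cells or second cell population was analysed here, so background could not be measured in a control.

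The authors deposited 1 table per library, with a running number and a whole-number count for each of 33643 features. Per the deposited text notes, each table is a quantification of enrichment, made from that library's alignments to mm10 together with a second file common to both tables, which is not used here. That the values are counts without normalization was inferred from the values: they are whole numbers, they sum to different totals, and in weak features the libraries differ by the amount that plain counts predict. In features with 40 counts or more over both libraries they differed by less than that. There the intervals and the binomial test described below overstate the noise between the libraries. Whether reads, fragments or other tags were counted is not given in the sources used here, and every CPM, interval and variance ratio treats 1 count as 1 independent event. The aligner, the treatment of duplicate reads, the definition of the features and the counting tool are not given in the sources used here. The tables pair the numbers with no gene, position or length. A feature is therefore taken to be a counted stretch of the genome of unknown place and size, and the reference annotation was not used. The counts over these features sum to 726464 in library 1 and 794443 in library 2, while the depth of the whole libraries is unknown.

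Before the data were examined, 5 kinds of result had been planned. Lists of regulatory T cell, other T cell, housekeeping and other cell type genes had been fixed, as had a rule for naming genes: Foxp3, Il2ra, Ctla4 and Ikzf2, the genes of the 10 strongest features, the extremes of each list, and the 3 features with the largest difference each way between the libraries. The 3 kinds of result that need gene names or positions (level of each list, list members with a feature, annotation classes) and every part of the naming rule were not analysed here. Features named by number below were chosen after their values were seen.

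The 2 planned results that remain compare the libraries. Pearson's correlation was computed across features on log2 of the count scaled to a library total of 1000000 (CPM), with a pseudocount of 1, and Spearman's correlation on the same values. Features are not independent replicates, so no p-value is attached. Each correlation was set beside 100 random splits of the summed counts into the 2 library totals, which show the value that counting noise alone allows. Each feature with at least 10 counts over both libraries was then tested with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment at 0.05. This test compares 2 libraries of 1 sample, not conditions. A variance ratio was added after the counts were seen. It is the squared difference of a feature's count from its expected share, divided by the binomial variance, averaged over features; 1 means counting noise alone.

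The binomial test was tested on simulated data, with Poisson counts for the 33643 features and 200 changed features in each of 20 runs. Of these, 100 were changed 2-fold and 100 were changed 4-fold, all drawn from features with at least 10 counts over both libraries. The test found 13.4% of the features changed 2-fold and 52.5% of those changed 4-fold, with a mean of 2.5 false calls per run. In 50 simulated pairs of libraries with no change the variance ratio averaged 1.00.

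Alternatives were linear values, a pseudocount of 0.1, scaling by median ratio (DESeq2 1.42.0) or TMM (edgeR 4.0.16), no count minimum, a minimum of 50 counts, and a 1.5-fold minimum. Both packages supplied scaling factors only, since 1 library on each side leaves no spread for their tests. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3, were used. Shares are given with 95% Wilson intervals. Intervals and limits cover counting error only, as molecular identifiers are not mentioned in the sources used here. Intervals of the strongest features and of top shares take the ranking as fixed.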

Results

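H3K27 acetylation, a histone mark found at active promoters and enhancers, was profiled in inflammation-experienced regulatory T cells, the T cell lineage defined by the transcription factor Foxp3 that restrains immune responses. The data are 2 technical libraries from 1 biological sample, counted over the same 33643 numbered features. The counts summed to 726464 in library 1 and to 794443 in library 2, 1.09 times as many. The labels give 1 cell population, so the design holds no contrast of conditions. The comparisons it allows are between features within a library and between the libraries, which asks how closely technical replicates of 1 sample matched. Which steps of the procedure the technical replicates repeat separately was not examined here. The features carry no gene names or positions in these tables, so acetylation at Foxp3, Il2ra, Ctla4 or any other gene was not analysed here.

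H3K27ac counts were spread unevenly over the features. The median feature held 12 counts in library 1 and 13 in library 2, and the mean feature held 21.6 and 23.6. Features at the 90th percentile held 55 counts in library 1 and 60 in library 2, while those at the 10th percentile held 3 in each. The strongest 3364 features, the top 10%, held 37.8% of the counts in library 1 (95% Wilson interval 37.7% to 38.0%) and 37.4% in library 2 (37.3% to 37.6%). With features ranked in library 1 and counted in library 2, so that the ranking did not use the same counts, the share was 36.7% (36.6% to 36.8%). This share lies below both earlier intervals, which leave out the error from ranking and counting in the same library. The strongest 336 features, the top 1%, held 6.48% in library 1 (6.43% to 6.54%) and 6.41% in library 2 (6.35% to 6.46%). These intervals leave out the same error, and no share across libraries was computed for the top 1%. The variance of the counts across features was 29.0 times their mean in library 1 and 30.9 times in library 2, whereas counts of equal features would give about 1. Feature lengths are not given and no control library was used. Uneven acetylation therefore cannot be told here from uneven feature length or background, and a strong feature means only one with a high count.

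Most of the strongest features by count were shared by the libraries. Feature 6635 ranked highest, with 505 counts in library 1 and 522 in library 2. These were 695 CPM, counts scaled to a library total of 1000000 (95% Wilson interval 637 to 758), and 657 CPM (603 to 716), and 42.1 and 40.2 times the library's median feature. Feature 18076 followed with 400 and 430 counts, or 551 CPM (499 to 607) and 541 CPM (492 to 595). For both features the intervals of the libraries overlapped. Of the 336 strongest features of each library, 257 were shared. Independent lists of that size would share 3.36, but libraries of 1 sample were bound to exceed that. The overlap given by random splits of the summed counts was not computed.

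Few features had an H3K27ac count of 0. A count of 0 was recorded in 290 features of library 1, or 0.862% (95% Wilson interval 0.769% to 0.967%), and in 221 features of library 2, or 0.657% (0.576% to 0.749%). Only 18 features were at 0 in both. A count of 0 allows up to 3 counts, or 4.13 CPM in library 1 and 3.78 CPM in library 2, so such features were not detected at this depth. At least 10 counts were recorded for 57.4% of the features in library 1 and for 61.1% in library 2. How the features were chosen is not given in the sources used here, and counts may include background. The small share at 0 therefore cannot be read as widespread acetylation.

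The features fell into ranges of higher and lower H3K27ac count along their numbers. Features 1 to 20337 had a median of 41 counts over both libraries, and features 20338 to 33643 had a median of 14, with the boundary placed where the running sum of deviations from the mean log2 count was largest. The median was 19 against 7 counts in library 1 and 22 against 7 in library 2. The first range held 60.4% of the features and 81.7% of the counts. The ranges overlapped: 83.6% of features in the first range lay above the median of the second, and 9.91% of those in the second lay above the median of the first. None of 1000 shuffled orders gave a running sum as large, a permutation p of 0.001, the smallest they can give. The boundary was chosen from these counts. What orders the features and how long they are is not given in the sources used here, so a difference in count between the ranges cannot be told from a difference in feature length.

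**Figure D1:**
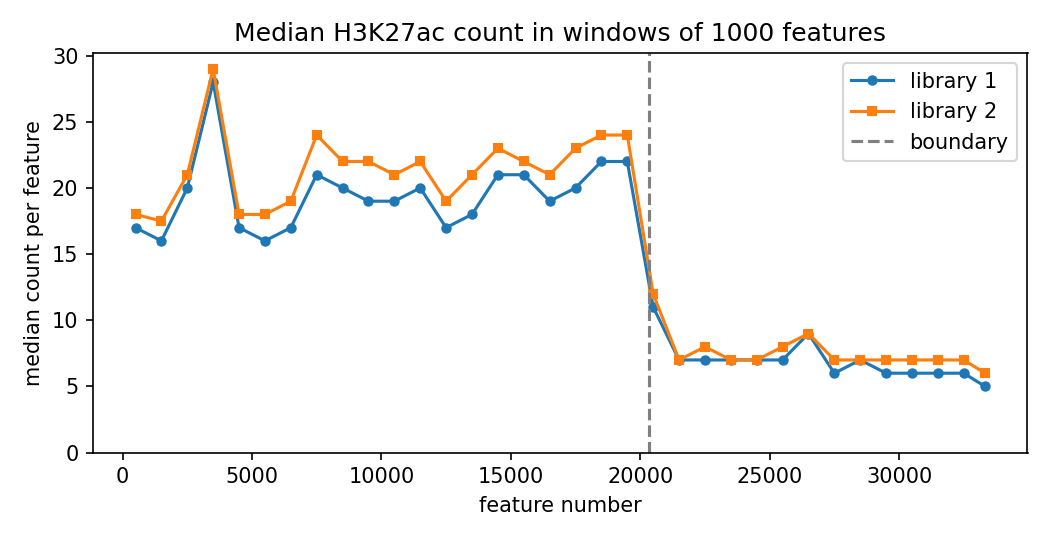
Median count per feature (vertical axis, counts) in windows of 1000 consecutive feature numbers (horizontal axis), for library 1 (circles) and library 2 (squares); the last window is shorter, and the dashed line marks feature 20337. Library 1 lies between 16 and 28 counts in the windows before the boundary and between 5 and 9 in those after the window that holds it.

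On the log2 and rank scales, H3K27ac counts in the libraries were correlated across features as closely as counting noise allows. Pearson's r was 0.899 on the log2 scale, and 100 random splits of the summed counts gave 0.896 to 0.901. Spearman's rho was 0.910, and the splits gave 0.909 to 0.912. On linear counts, which weight the strongest features, r was 0.970, above the 0.966 to 0.968 of the splits. These are correlations across features, which are not independent replicates.

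No feature passed the test for a difference in H3K27ac count between the libraries. Of 28062 features with at least 10 counts over both libraries, 0 passed the exact binomial test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.966. At an unadjusted p under 0.05 there were 983 features, 493 of them higher in library 2 and 490 higher in library 1 relative to the totals. Random splits gave 1073 to 1210 such features, more than were observed. In simulated libraries of this depth the test found 13.4% of features changed 2-fold and 52.5% of those changed 4-fold. These are means over features with at least 10 counts, with 100 changes of each size planted together. Averaged over such features, a 2-fold difference would therefore mostly have gone undetected. The rate in strong features alone was not computed.

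The difference between the libraries was smaller than counting noise in features with many counts. Over the 28062 tested features the variance ratio was 0.951 ± 0.00794 (SE over features), and random splits gave 0.986 to 1.02. Features with 5 to 9 counts over both libraries had a ratio of 0.987 ± 0.0199, those with 10 to 19 counts 1.02 ± 0.0150 and those with 20 to 39 counts 1.00 ± 0.0160, each within 2 SE of 1. The ratio was 0.914 ± 0.0175 in features with 40 to 79 counts, 0.827 ± 0.0168 with 80 to 159 counts and 0.814 ± 0.0300 with 160 to 319 counts. In the 64 features with 320 counts or more it was 0.799 ± 0.117, within 2 SE of 1. The labels give both libraries the same biological sample, so they were counted as 1 sample and no SD between samples is given. All intervals here describe counting error in 1 biological sample and say nothing of the spread between animals.

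**Figure D2:**
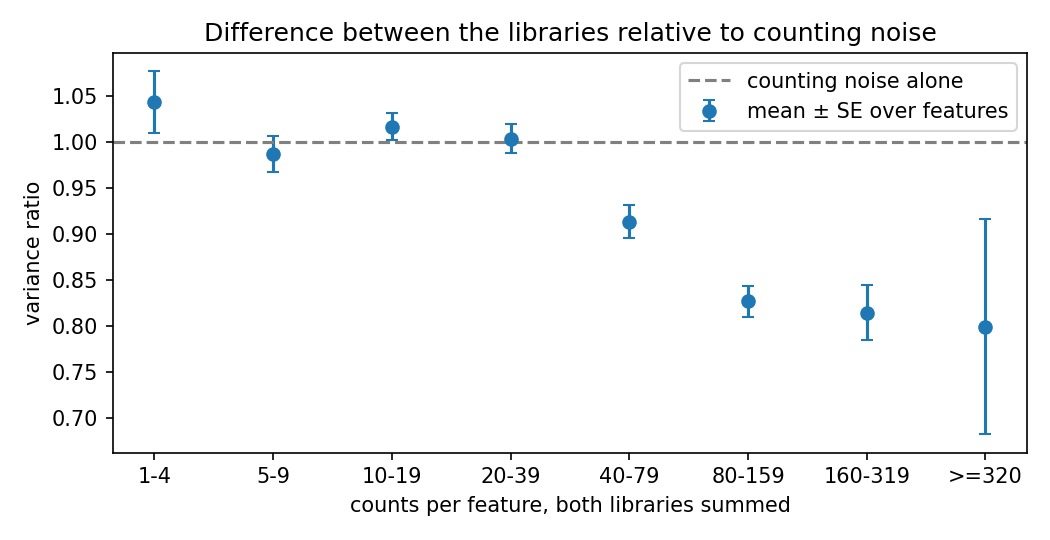
Variance ratio of the 2 libraries (vertical axis, no unit) for features grouped by their summed count (horizontal axis, counts per feature). Points are means over features, bars are the SE over features, and the dashed line at 1 marks counting noise alone. The points lie near 1 up to 39 counts and fall to 0.827 at 80 to 159 counts. They change little above that, with 0.814 at 160 to 319 counts and 0.799 ± 0.117 at 320 or more.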

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

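The alternatives for the variance ratio, the top share and the step along the feature number were chosen after the data were seen; those for the correlation and the binomial test were fixed beforehand. The correlation of the libraries depended on how weak features were weighted: Pearson's r was 0.899 as reported, 0.970 on linear values, 0.902 with at least 10 counts and 0.842 with a pseudocount of 0.1. The binomial test called 0 features under median ratio scaling, TMM scaling, no count minimum and a minimum of 50 counts; an added 1.5-fold minimum can only remove calls and so tested nothing. At an unadjusted p under 0.05 the scalings gave 982 and 983 features and no minimum gave 1119, while the minimum of 50 counts left 9794 features and gave 285. The variance ratio of 0.951 stayed below 1 by more than 2 SE with both scalings and with no minimum (0.959). It also stayed below 1 with a library ratio per count class, but such a fit cannot raise a low ratio to 1. The minimum of 50 counts (0.856) kept mainly features already seen to have low ratios. Neither of these settings was therefore a test. The variance ratio was 0.924 in the first 20337 feature numbers and 1.00365 in the other 13306, which hold few strong features. At 80 to 159 counts it was 0.827 ± 0.0176 (SE) in 4163 features of the first range and 0.822 ± 0.0576 in 342 of the second. The share of counts in the top 10% of features was 37.4% to 37.8% with either library left out, and the ratio of medians across the step was 2.71 to 3.14. Placed from library 1 alone, the boundary of the step lay at feature 20222, and from library 2 alone at 20337. Settings that need gene names, lengths or positions were not run, nor were those for peak lists, since the files hold counts. No paired analysis was possible because there is 1 group.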

Other observations

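The tests of shared reads, of counting each position once, of random order and of a single library were chosen only after the results they bear on were seen. The same holds for the argument on background. The test of a joined numbering was written down first.

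H3K27ac counts stepped down after feature 20337, where the largest running sum of deviations from the mean log2 count was 11199, against 595 for the highest of 1000 shuffled orders (permutation p = 0.001, the smallest they can give). The step was not due to a single library, since the ratio of medians was 2.71 in library 1 and 3.14 in library 2. A candidate explanation is that the numbering joins 2 lists of features, each in the same order. The count profiles of the ranges, in 50 bins each, correlated at 0.132, and 9 of the 50 circular shifts gave as much, the real one included, so this stays open. Whether the ranges differ in feature length or in kind of element cannot be tested without their positions, and the design gives no biological contrast to set against it.

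Counts of adjacent features were weakly correlated. In the first range the correlation of log2 counts between adjacent numbers was 0.08, against at most 0.02 in 100 shuffled orders, and in the second range 0.14, also against 0.02. At a distance of 10 numbers it was 0.038 and 0.063, against at most 0.020 and 0.021 in shuffled orders. At a distance of 100 it was 0.0034 in the first range, under the highest shuffled value of 0.027, and 0.030 in the second, above the highest of 0.017. At a distance of 500 it was -0.0029 and 0.0018, between the lowest shuffled values of -0.015 and -0.031 and the highest of 0.019 and 0.023.

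The libraries differed by less than counting noise in strong features, as reported above: the variance ratio was 0.823 ± 0.0146 (SE) in the 6014 features with 80 counts or more. If the same reads had entered both libraries, at an equal share in every feature, the ratio would be lowered by the same share at every count. It was 1.01 ± 0.0109 in features with 10 to 39 counts, which argues against such even sharing as the whole cause. A different background share would add to the difference between the libraries, so by itself it would not lower the ratio. This is an argument and not a test, because the ratio of 0.823 is the pattern to be explained. A test written down first, with a library ratio per count class, moved the ratio only to 0.820 and is not used as evidence. Counting each position only once, as duplicate removal does, may contribute, since it would bring the libraries closer together in strong features. Their count ratio was 1.09 ± 0.00217 there against 1.10 ± 0.00269 in features with 10 to 79 counts, a difference of log ratios of 0.0165 ± 0.00316. A different background share could also shift the count ratio, so the difference does not by itself point to counting each position once. At similar feature lengths such counting would lower the variance ratio further as counts rise. The ratio was 0.827 ± 0.0168 at 80 to 159 counts, 0.814 ± 0.0300 at 160 to 319 and 0.799 ± 0.117 at 320 or more, with no clear further fall. Feature lengths are not given, so these values cannot settle it. A simple saturation model predicts a count ratio of 1.093 in strong features and the observed value was 1.085. No error was computed for the prediction. The model also takes features with 10 to 79 counts as unsaturated, although the variance ratio was already 0.914 at 40 to 79 counts. Whether saturation, a background difference or both give the observed count ratio therefore stays open. No biological explanation was tested, because both libraries come from 1 sample.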
